A study of Micropterus salmoides with 164 samples.

How the data were processed

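The study measured polyadenylated RNA of gill and spleen in largemouth bass before and 12 and 24 h after bacterial challenge, by paired reads of 150 bp. Of 164 libraries in the labels 161 were analysed, and 3 gill libraries that the authors excluded are absent from the count tables. Per the submitters' processing notes, reads passed FastQC, MultiQC and fastp, Salmon quantified transcripts, and DESeq2 gave the contrasts. No versions or genome build are given in the sources used here.

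The deposited count tables hold estimated counts per gene, made by the authors with Salmon, and all values in them were whole numbers (0 non-integers). They held 23561 genes in gill and 22355 in spleen. The deposited contrast tables hold the authors' DESeq2 log2 fold changes, used here only for a comparison of gene calls at an absolute log2 fold change above 1. The adjusted p-values in these tables were also made by the authors with DESeq2. The authors' table of numbers of genes per contrast, per the file headers, was made from these 2 columns, and a recount here gave its numbers in every contrast. Of the genes called here against Mock at the same fold change, the authors' tables held 43.1% (Fc at 24 h) to 93.8% (Ah at 24 h) in gill and 69.8% (Ah at 24 h) to 91.9% (Fc at 24 h) in spleen. Variance-stabilized tables were not used here. The labels call the Mock fish sham-injected while the protocol describes immersion, and they give 2 species names for the bass.

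Gene symbols, zebrafish ortholog symbols and group names came from the deposited annotation and the RefSeq gene table, in which all 24710 counted genes were found. Of these 12723 had a symbol of their own, 5419 had only a zebrafish ortholog symbol and 3864 only a group name. The 27 gene lists held 1178 of the genes. A column that excludes some product names was added to the lists once the tables had been opened and before any list was tested.

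All libraries of a tissue went into 1 fit with a mean per group (13 groups), in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15, large group 10, proportion 0.7), which left 22123 in gill and 20540 in spleen. Libraries were scaled by TMM, and contrasts were tested with quasi-likelihood F tests at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were each infection against Mock, each coinfection against its single infections, the departure of each coinfection from the sum of the single effects, Mock against Pre, Av against Ah, and infection effects by time. The standard error of a log2 fold change was its size divided by the square root of F. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and 553 list calls were made with the first. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

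Genes were named by a rule fixed before the files were opened. It took called genes with a mean of at least 1 log2 CPM, a name, and, for contrasts of 2 groups, all libraries of the first group on one side of the mean of the second. For each pair of hours the hour with more calls was used. Genes were ranked by absolute change, with 6 each way for an infection, 3 or 4 for other contrasts, and the 6 smallest p for time. Called members with the largest change could stand as examples of a list. The rule took 226 genes, of which 121 lost their call when some library was left out, and 202 list examples, of which 35 did. Most of those are not named, and a named gene kept its call in every leave-out unless the text says otherwise. Calls were also lost under alternatives that the report does not repeat. With limma-voom these were gill fosb and fosl1a for Ah at 12 h, gill fosb for Av against Ah, gill LOC119886878 for AhFc against Ah, gill irg1l for AvFc against Av, hepcidin for AvFc against Fc, spleen leap2 and spleen rundc3aa. In fits of only the groups named they were fosb, fosl1a, LOC119886878, leap2 and rundc3aa. With the library letter as a random block collagenase 3 lost its gill AvFc non-additivity call, and with the replicate block snx10b, tacc3, tfa and rundc3aa lost theirs. Without libraries rich in ribosomal protein transcripts leap2 and rundc3aa lost theirs. Where one group had 0 counts a bound was given, from a floor of 3 counts over the group.

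Alternatives chosen in advance were DESeq2 1.42.0, DESeq2 size factors, no count filter, a fit of only the groups named, the replicate number as a block, limma-voom, and limma-voom with the library letter as a random block. Added after the data were seen were leaving out libraries with a ribosomal protein share over 2 times the tissue median, and thinning deeper libraries to the median depth. Each library was also left out in turn. Group labels were redrawn for 50 splits per contrast, the real one included. On simulated data made from these counts, the test of Av against Mock at 12 h recovered 51% of genes changed 2-fold and 88% of those changed 4-fold in gill with 9 false calls, and 35% and 85% in spleen with 4. DESeq2 made 43 false calls in the gill test.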

Results

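Gill and spleen of largemouth bass were profiled by RNA sequencing before a bacterial challenge (Pre) and 12 and 24 h after it. Fish met Flavobacterium columnare (Fc), either of A. veronii (Av) and A. hydrophila (Ah) of the genus Aeromonas, or Fc together with the one (AvFc) or the other (AhFc). Controls had a mock treatment (Mock). The labels describe immersion in the protocol and a sham injection for Mock, so the route of the mock treatment is unclear. The 161 libraries analysed here held 79 of gill, with 11.3 to 54.8 M counts (median 16.1 M), and 82 of spleen, with 13.1 to 34.2 M (median 17.05 M). Each group had 6 libraries, except Pre with 10 per tissue and gill Mock at 12 h, Ah at 12 h and AhFc at 24 h with 5, after the authors had excluded 3 gill libraries. The labels call the replicates biological and mark them with a letter and a number (such as A1), but nothing in them says whether a letter stands for a tank, so the p-values measure only the spread between these samples. Each challenge group was compared with Mock of the same tissue and hour, then each coinfection with its single infections, by a quasi-likelihood test in edgeR on all genes that passed the count filter (22123 in gill, 20540 in spleen). Log2 fold changes are given ± SE, levels in CPM as mean ± SD, and the 27 gene lists were written before the data were examined, apart from some excluded product names.

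Av infection raised the iron-withholding gene hepcidin in the gill. At 24 h hepcidin (LOC119897237), the peptide hormone that blocks iron export from cells, stood at 215 ± 164 CPM against 0.197 ± 0.186 CPM in Mock, a log2 fold change of 10.05 ± 1.28 (adjusted p = 4.44e-08). A gene annotated as CEACAM20 (LOC119897359), of a family of cell adhesion proteins, rose from 1.22 ± 0.917 to 354 ± 176 CPM (8.18 ± 0.89, adjusted p = 4.78e-10), and thymidine phosphorylase (LOC119895074), an enzyme of nucleoside breakdown, by 9.89 ± 1.47 (adjusted p = 1.6e-06). Haptoglobin (LOC119890332), which binds free hemoglobin, had 0 counts in the 6 Mock libraries and was at least 233-fold higher (adjusted p = 0.00771), a call that limma-voom did not make. A C1q and TNF related gene (LOC119894942) fell by 4.70 ± 1.36 (adjusted p = 0.0129), and this call too was lost with limma-voom. At 12 h the lymphatic endothelial receptor genes lyve1a (3.96 ± 0.66, adjusted p = 4.55e-05) and stab2 (1.71 ± 0.33, adjusted p = 0.000302) rose. In all, 1244 genes were called higher and 1016 lower at 12 h, and 1583 and 1300 at 24 h. The 2260 calls at 12 h became 1475 without Av E1 and 1394 without Mock A3.

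Ah infection raised the iron-withholding gene hepcidin in the gill at 12 h. Hepcidin (LOC119897237) rose by 8.34 ± 1.33 at 12 h (adjusted p = 3.05e-05), thymidine phosphorylase (LOC119895074) by 7.78 ± 1.36 (adjusted p = 0.000125), the receptor gene HCAR2 (LOC119916475) by 6.84 ± 1.15 (adjusted p = 6.8e-05) and the CEACAM20 gene (LOC119897359) by 6.41 ± 0.89 (adjusted p = 4.25e-06). Of these only the last was called by limma-voom with the library letter as a random block. TMPRSS9 (LOC119896549), a membrane-bound serine protease, fell from 281 ± 168 CPM in Mock to 13.2 ± 8.83 CPM (log2 fold change -4.42 ± 0.99, adjusted p = 0.00315). The immediate early genes fosl1a (7.05 ± 1.32, adjusted p = 0.000302) and fosb (6.28 ± 1.00, adjusted p = 3.05e-05) were called only with library Ah J3, and without it their adjusted p was 0.0649 and 0.053. At 12 h 752 genes were called higher and 146 lower, and at 24 h 136 and 9. The 898 calls at 12 h became 1862 without Ah J1, 578 without Mock A2 and 537 without Mock A3. It became 320 without Ah J3, and the 145 at 24 h became 43 without Ah T3.

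By 24 h Fc gill had cell division genes above Mock, itself below Pre for them. Collagenase 3 (LOC119896105), a secreted protease of collagen, rose by 7.82 ± 1.20 (adjusted p = 1.05e-05), with 1 library (M3) at 2660.0 CPM. The complement gene c7b, part of the membrane attack complex, rose by 6.64 ± 0.99 (adjusted p = 6.42e-06), hepcidin (LOC119897237) by 6.77 ± 1.20 (adjusted p = 0.00014) and thymidine phosphorylase (LOC119895074) by 8.55 ± 1.45 (adjusted p = 8.08e-05). The last 2 were not called by limma-voom. Among 64 measured cell cycle genes 36 rose and 1 fell at 24 h (45 and 1 adjusted over the list alone, median log2 fold change 0.97), including the replication licensing gene cdc6 (1.82 ± 0.32, adjusted p = 0.00012), cdk1 (1.42 ± 0.33, adjusted p = 0.00221) and birc5a (1.53 ± 0.37, adjusted p = 0.00338). The list test called this rise (camera, adjusted p = 2.08e-13, and 0.272 with an estimated correlation). At 12 h 1527 genes were called higher and 670 lower, and at 24 h 2316 and 1343. A fit of Fc and Mock alone called 0 genes at 12 h, and the 2197 calls there became 3310 without Fc M3, 1194 without Mock B1 and 1094 without Mock A2. It became 1018 without Fc N3, 738 without Mock A1, 698 without Mock A3 and 142 without Fc M1. The 3659 calls at 24 h became 2350 without Mock B2 and 1284 without Fc M3.

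AvFc coinfection of the gill gave 3905 genes higher and 3068 lower at 24 h. Thymidine phosphorylase (LOC119895074) rose by 10.38 ± 1.48 (adjusted p = 6.94e-07), hepcidin (LOC119897237) by 9.81 ± 1.28 (adjusted p = 7.99e-08), HCAR2 (LOC119916475) by 7.91 ± 1.13 (adjusted p = 7.18e-07) and the CEACAM20 gene (LOC119897359) by 7.82 ± 0.87 (adjusted p = 1.56e-09). The itaconate-producing enzyme gene acod1 rose by 7.06 ± 0.94 (adjusted p = 1.69e-07), the epithelial cytokine gene il17c by 5.39 ± 0.81 (adjusted p = 2.23e-06), from a Mock level below that of Pre, and a CXCL2-like chemokine gene (LOC119899104) by 5.89 ± 1.27 (adjusted p = 0.000337). An endonuclease domain gene, ENDOD1 (LOC119913010), fell by 3.54 ± 1.06 (adjusted p = 0.00762). At 12 h 780 genes were called higher and 352 lower, and these 1132 calls became 726 without Mock A3 or AvFc P2. A fit of AvFc and Mock alone called 2351 genes at 12 h. Library AvFc P3 carried 14.8% of its counts on ribosomal protein genes and 5.03% on erythrocyte genes, more than the other libraries of its group.

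AhFc coinfection of the gill gave 1731 genes higher and 1139 lower at 12 h, and 1637 and 996 at 24 h. At 12 h hepcidin (LOC119897237) rose from 0.225 ± 0.205 CPM to 142 ± 70.8 CPM, by 9.23 ± 1.35 (adjusted p = 3.25e-06), thymidine phosphorylase (LOC119895074) by 8.64 ± 1.38 (adjusted p = 1.75e-05) and the metalloreductase gene steap4, of cellular iron uptake, by 5.94 ± 0.78 (adjusted p = 3.47e-07). Collagenase 3 (LOC119896105) rose to 1490.0 ± 3020.0 CPM (adjusted p = 2.2e-05), with R1 at 7640.0 and the next library at 424 CPM, and by 5.47 without R1. Calpain-1 (LOC119910299), a calcium-dependent protease, fell by 3.78 ± 0.90 (adjusted p = 0.00321) and ADAMTS16 (LOC119897891), a matrix protease, by 2.65 ± 0.59 (adjusted p = 0.00154). The 2870 calls at 12 h became 1727 without Mock A3 and 1212 without AhFc R1, and the 2633 at 24 h became 1587 without Mock B2, 990 without AhFc R1 and 794 without AhFc Q3.

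**Figure D1:**
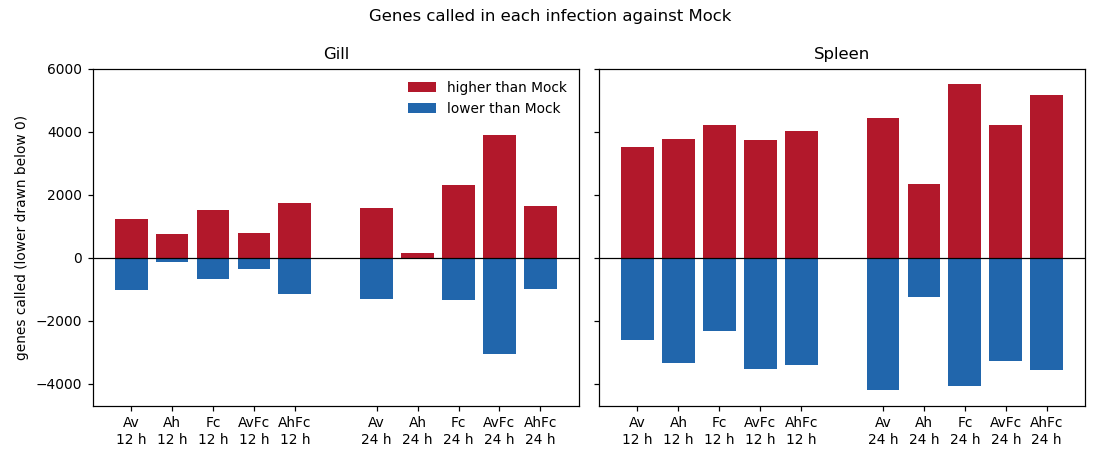
Numbers of genes called higher (up) and lower (down) in each infection against Mock of the same tissue and hour, at adjusted p under 0.05. Gill and spleen stand side by side, at 12 and 24 h.

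Innate immune lists rose in the gill, as counts of members and in the list test (camera with a preset correlation of 0.01). Of 30 measured complement genes 3 to 14 rose per comparison (3 to 17 adjusted over the list alone), led after AvFc at 24 h by c7b (7.03 ± 1.00, adjusted p = 7.57e-07) and the C5a receptor gene LOC119883099 (3.62 ± 0.53, adjusted p = 1.24e-06). The list was called in 9 of 10 comparisons (adjusted p = 1.27e-07 to 0.00573), and with an estimated correlation after Av at 12 h (adjusted p = 0.0441) and 24 h (0.0416), the others having adjusted p = 0.0511 to 0.272. Acute phase and iron-withholding genes (29) had 3 to 10 members rising and 0 falling (3 to 14 rising over the list alone), called in all 10 comparisons (adjusted p = 1.71e-08 to 0.00982), with adjusted p = 0.0325 with an estimated correlation at 12 h after all but Fc and 0.0928 to 0.286 in the rest. The call after AhFc at 24 h (0.00982) was lost with limma-voom and in a fit of the 2 groups alone. Cytokine receptor and feedback genes (44) rose in 4 to 31 members (6 to 32), such as the IL-1 decoy receptor (LOC119904450, 6.94 ± 1.07, adjusted p = 3.22e-06), CXCR2 (LOC119903646, 4.63 ± 0.62, adjusted p = 1.92e-07) and socs3a (2.92 ± 0.56, adjusted p = 8.96e-05) after AvFc at 24 h. Their 10 list calls (adjusted p = 2.23e-13 to 2.78e-05) held with an estimated correlation after Ah, AvFc and AhFc at 12 h (adjusted p = 0.0416 to 0.0441) and not elsewhere (0.0602 to 0.244). Neutrophil genes (40) rose in 8 to 22 members (12 to 25), with collagenase 3 (LOC119896105) at 7.58 ± 1.19 (adjusted p = 4.43e-06) after AvFc at 24 h. All 10 neutrophil calls (adjusted p = 1.83e-13 to 3.17e-05) were lost with an estimated correlation except AhFc at 12 h (adjusted p = 0.0475, the others 0.0602 to 0.284). Macrophage and dendritic genes (31) rose in 2 to 15 members (2 to 18), among them the scavenger receptor gene marco (2.59 ± 0.35, adjusted p = 1.92e-07) and a mannose receptor (LOC119901899, 2.81 ± 0.41, adjusted p = 1.28e-06) after AvFc at 24 h. They were called in all comparisons but Fc at 12 h (adjusted p = 1.33e-09 to 0.00758), with an estimated correlation after Av at 12 and 24 h (adjusted p = 0.0397 to 0.0441, the others 0.0511 to 0.349).

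Lymphocyte and antigen presentation lists fell in the gill, though every such call was lost with an estimated correlation. Of 27 T cell genes 0 to 14 fell and 0 to 2 rose (0 to 20 falling over the list alone), with il2rb at -1.56 ± 0.37 (adjusted p = 0.00109) and cd27 at 1.48 ± 0.27 (adjusted p = 3.4e-05) after AvFc at 24 h. All 10 comparisons were called (adjusted p = 5.15e-08 to 0.000346, and adjusted p = 0.19 to 0.419 with an estimated correlation). B cell and plasma cell genes (36) were called lower at 24 h, with 7, 0, 7, 9 and 6 falling after Av, Ah, Fc, AvFc and AhFc (11, 0, 9, 9 and 9 over the list alone, adjusted p = 3.58e-05 to 0.0183, and adjusted p = 0.155 to 0.439 with an estimated correlation). An immunoglobulin lambda gene (LOC119907221) fell by 2.37 ± 0.49 (adjusted p = 0.000227) and cxcr5 (LOC119882892) by 2.00 ± 0.46 (adjusted p = 0.000731) after AvFc. MHC class II genes (34) fell in 10 and rose in 3 members after Av at 24 h (11 and 4, adjusted p = 0.00789, and adjusted p = 0.481 with an estimated correlation), a class II chain (LOC119917261) falling by 1.97 ± 0.60 (adjusted p = 0.0196) and cathepsin L (LOC119892265) rising by 2.01 ± 0.34 (adjusted p = 1.76e-05). MHC class I genes (38) fell in 8 members after Av at 24 h (8 over the list alone, adjusted p = 0.000242, and adjusted p = 0.207 with an estimated correlation), and after AvFc nlrc5, the class I transactivator, fell by 1.37 ± 0.31 (adjusted p = 0.000557). Without Av F1 the B cell call after Av had adjusted p = 0.0693. Interferon-stimulated genes were called lower after Fc and AhFc at 12 h, with 3 and 7 falling (1 and 9, adjusted p = 0.00413 to 0.0265, and adjusted p = 0.554 to 0.62 with an estimated correlation), the second lost without AhFc Q2 (0.0538).

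Metabolic and stress lists rose against Mock in the gill. Of 53 oxidative phosphorylation genes 39 rose 24 h after Fc, 49 after AvFc and 16 after AhFc (46, 50 and 20 over the list alone). Heat shock and unfolded protein genes (56) rose in 18, 35 and 20 members (22, 37 and 24), among them hsp90aa1.1 (2.69 ± 0.68, adjusted p = 0.00188) after AvFc, and in 14 after Av (18). Glycolysis and hypoxia genes (47) rose in 13 members after Fc and 15 after AvFc at 24 h (17 and 17), where pfkfb3, an activator of glycolysis, rose by 4.39 ± 0.68 (adjusted p = 3.84e-06), while 5 fell. The list test called these 9 rises (adjusted p = 6.84e-18 to 0.0172, and 0.198 to 0.554 with an estimated correlation). Cell cycle genes fell at 12 h in 15 members after Av, 3 after Ah, 1 after AvFc and 12 after AhFc (27, 22, 0 and 12, adjusted p = 4.86e-09 to 1.96e-05, and adjusted p = 0.404 to 0.558 with an estimated correlation). At 24 h they rose in 3, 0, 16 and 6 (1, 0, 16 and 6, adjusted p = 8.73e-05 to 0.00808, and adjusted p = 0.582 to 0.688 with an estimated correlation), the Ah call lost without T2 (0.137).

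In the gill cartilage and bone genes (25) fell in 12 members after AvFc and 11 after AhFc at 24 h (13 and 12 over the list alone, adjusted p = 7.09e-06 to 0.000124, and adjusted p = 0.19 to 0.272 with an estimated correlation), such as matn4 (-2.71 ± 0.52, adjusted p = 8.57e-05) and a type XI collagen gene (LOC119901832, -2.44 ± 0.46, adjusted p = 6.51e-05) after AvFc. Erythrocyte genes (38) fell in 12 members after AhFc at 24 h (14, adjusted p = 0.000583, then 0.501 with an estimated correlation). Epithelial barrier genes (92) fell in 13 members after Av at 12 h and 12 at 24 h (15 and 19, adjusted p = 0.000897 to 0.00741, and adjusted p = 0.207 to 0.324 with an estimated correlation). Endothelial genes (27) rose in 7 members after Av at 12 h (9, adjusted p = 1.37e-05, then 0.266). Thrombocyte genes (14) fell in 3 members after AhFc at 24 h (3, adjusted p = 0.00655, and adjusted p = 0.402 with an estimated correlation), and nfe2 fell by 1.71 ± 0.41 (adjusted p = 0.000994) after AvFc. After AvFc at 24 h several lists had members on both sides and no list call. These were inflammatory cytokines (22 of 64 higher and 5 lower, adjusted p = 0.147), interferon-stimulated genes (4 and 11 of 60, 0.115), pattern recognition genes (9 and 7 of 50, 0.669), extracellular matrix genes (10 and 14 of 60, 0.418) and ion transport genes (9 and 4 of 54, 0.556). Matrix members included tnc (-2.76 ± 0.53, adjusted p = 7.72e-05), and ion transport members fxyd5 (1.71 ± 0.25, adjusted p = 1.58e-06) and clcn2a (-2.62 ± 0.67, adjusted p = 0.00192). Liver genes (4 and 0 of 14, adjusted p = 0.395) and exocrine pancreas genes (4 and 5 of 22, 0.349) were not called either. Antimicrobial effector genes (37) rose in 5 members after Ah at 24 h (8, adjusted p = 0.00402, and adjusted p = 0.0602 with an estimated correlation), while their medians at 12 h were below 0 after Av, Ah, Fc and AvFc and the test statistic, uncalled, was positive. Skeletal muscle genes (54) rose in 1 member and fell in 1 after AvFc at 12 h (1 and 1 over the list alone), where the test gave a fall (adjusted p = 0.000558, and adjusted p = 0.616 with an estimated correlation) against a median of 0.13, a call that DESeq2 fold changes did not give.

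**Figure D2:**
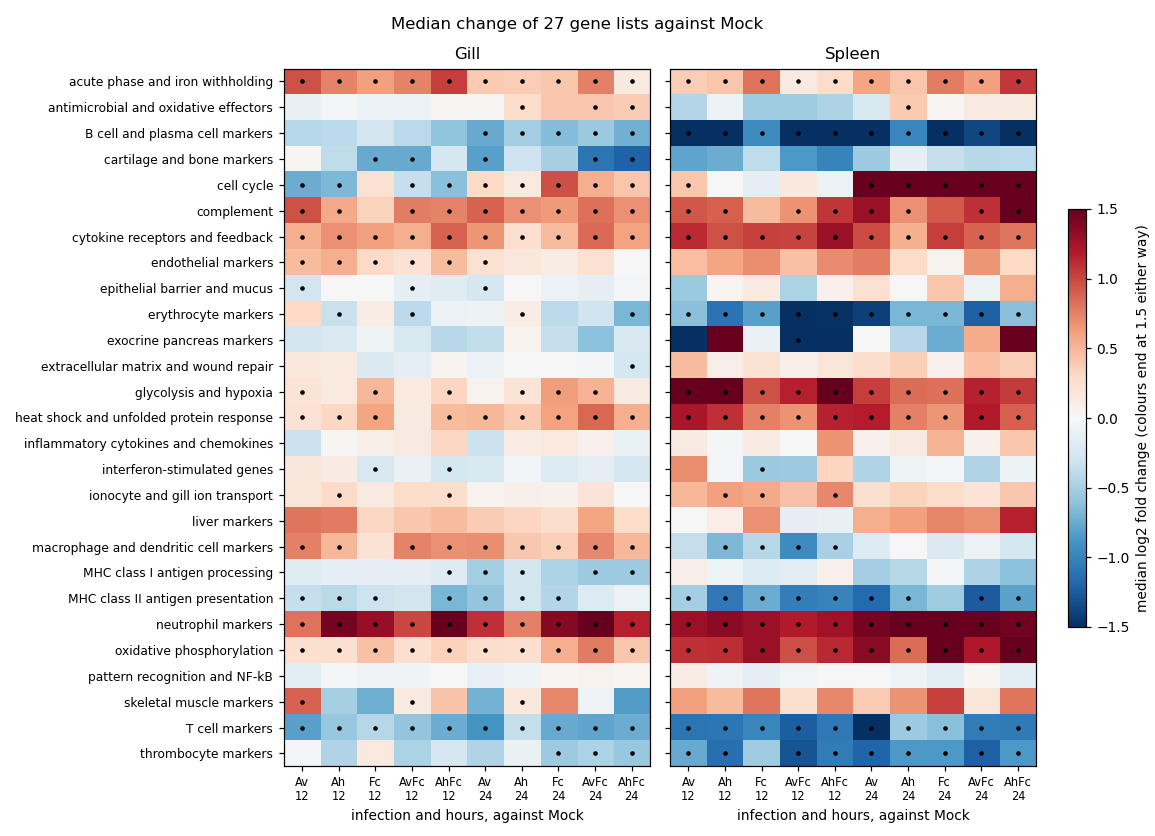
Median log2 fold change of each gene list in each infection against Mock, with colours ending at ±1.5. A dot marks a list called by camera with the preset correlation, and most of these calls were lost with an estimated correlation.

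In the spleen Av infection gave 3499 genes higher and 2604 lower at 12 h, and 4437 and 4209 at 24 h. At 24 h steap4, of cellular iron uptake, rose from 0.924 ± 0.487 CPM to 1050.0 ± 363 CPM, by 10.15 ± 0.77 (adjusted p = 1.59e-16), acod1 by 11.48 ± 1.23 (adjusted p = 1.95e-11), haptoglobin (LOC119890332) by 10.42 ± 1.56 (adjusted p = 1.82e-07) and a MFAP4-like gene (LOC119915509), of a family of fibrinogen-related lectins, by 10.11 ± 1.35 (adjusted p = 1.09e-08). The vitamin D degrading enzyme gene cyp24a1 (LOC119885885), with 0 counts in the 6 Mock libraries, was at least 1170.0-fold higher (adjusted p = 7.12e-06). A type I deiodinase gene (LOC119918671), of thyroid hormone conversion, fell (adjusted p = 3.42e-05). B cell genes fell, with the lineage factor genes pax5 at -4.85 ± 0.79 (adjusted p = 8.93e-07) and ebf1a at -4.22 ± 0.69 (adjusted p = 1.24e-06) and the antigen receptor gene cd79a at -4.37 ± 0.69 (adjusted p = 5.56e-07). Egg coat genes of the ZP3 family that the named-gene rule took as falling rested on Mock library A3, and without it the calls of LOC119899592, LOC119902501 and LOC119899595 had adjusted p = 0.0791, 0.376 and 0.483.

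Ah infection of the spleen gave 3782 genes higher and 3344 lower at 12 h, and 2355 and 1261 at 24 h. At 12 h igfbp1a, which binds insulin-like growth factors, rose by 10.02 ± 1.84 (adjusted p = 2.2e-05), the IL-13 decoy receptor gene il13ra2 by 9.95 ± 1.38 (adjusted p = 7.49e-08), the MFAP4-like gene (LOC119915509) by 9.68 ± 1.36 (adjusted p = 1.08e-07) and haptoglobin (LOC119890332) by 9.36 ± 1.49 (adjusted p = 1.71e-06). The sodium pump interacting gene nkain4 rose by 5.61 ± 0.95 (adjusted p = 5.46e-06) and the sodium-hydrogen exchanger NHE3 (LOC119908031) by 4.09 ± 0.99 (adjusted p = 0.000851). The 6 largest falls, 3 of them egg coat (ZP3 or ZP4) genes, rested on Mock library A1, and without it their adjusted p was 0.0739 to 0.312. A fit of Ah and Mock alone called 7461 genes at 24 h.

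Fc infection of the spleen gave 4223 genes higher and 2315 lower at 12 h, and 5517 and 4063 at 24 h. At 24 h acod1 rose by 9.23 ± 1.18 (adjusted p = 5.49e-09), an amino acid decarboxylase gene, GADL1 (LOC119898108), by 8.88 ± 0.89 (adjusted p = 3.38e-12), steap4 to 420.0 ± 177 CPM (8.82 ± 0.74, adjusted p = 7.4e-15) and haptoglobin (LOC119890332) by 7.67 ± 1.42 (adjusted p = 9.73e-06). The guanine nucleotide exchange factor gene rasgrf2a fell by 5.21 ± 0.74 (adjusted p = 5.34e-08), tetranectin (clec3ba) by 5.29 ± 1.18 (adjusted p = 0.000169), and the nucleic acid sensors tlr7 and tlr9 by 4.83 ± 0.75 (adjusted p = 3.89e-07) and 3.10 ± 0.57 (adjusted p = 7.93e-06). The 9580 calls at 24 h became 5589 without the libraries rich in ribosomal protein transcripts described below, an alternative added after seeing the data. The 6538 calls at 12 h became 4035 without Fc N2 and 3480 in a fit of Fc and Mock alone.

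AvFc coinfection of the spleen gave 3751 genes higher and 3532 lower at 12 h, and 4226 and 3276 at 24 h. At 24 h acod1 rose by 11.29 ± 1.23 (adjusted p = 3.87e-11), haptoglobin (LOC119890332) by 10.00 ± 1.54 (adjusted p = 4.81e-07), steap4 by 9.67 ± 0.76 (adjusted p = 7.11e-16) and the MFAP4-like gene (LOC119915509) by 9.59 ± 1.32 (adjusted p = 3.54e-08). At 12 h il13ra2 rose by 9.94 ± 1.38 (adjusted p = 6.73e-08) and the IL-1 decoy receptor (LOC119904450) by 7.23 ± 0.95 (adjusted p = 2.03e-08), while ciita, the class II transactivator, fell by 2.61 ± 0.44 (adjusted p = 5.37e-06) and the erythrocyte genes cahz (-3.27 ± 0.65, adjusted p = 6.59e-05) and ank1a (-2.83 ± 0.67, adjusted p = 0.000638) fell.

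AhFc coinfection of the spleen gave 4030 genes higher and 3395 lower at 12 h, and 5159 and 3574 at 24 h. At 24 h haptoglobin (LOC119890332) rose by 10.65 ± 1.58 (adjusted p = 2.78e-07) to 564 ± 969 CPM, and by 9.04 without Q3 (2470.0 CPM), a library with 27.8% of counts on ribosomal protein, 0.718% on pancreas and 0.211% on liver genes. Acod1 rose by 9.81 ± 1.19 (adjusted p = 2.32e-09), the MFAP4-like gene (LOC119915509) by 9.40 ± 1.31 (adjusted p = 8.07e-08) and steap4 by 8.76 ± 0.73 (adjusted p = 1.86e-14). The neutrophil enzyme genes mmp9 (4.73 ± 0.85, adjusted p = 9.27e-06) and collagenase 3 (LOC119896105, 6.37 ± 0.75, adjusted p = 9.46e-10) rose, and a C-type lectin-like gene annotated as type 2 ice-structuring protein (LOC119895468) fell by 5.19 ± 1.35 (adjusted p = 0.00139). At 12 h il11a rose by 8.25 ± 1.39 (adjusted p = 4.15e-06), and il17c, with 0 counts in the 6 Mock libraries, was called higher (adjusted p = 6.6e-08).

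**Figure D3:**
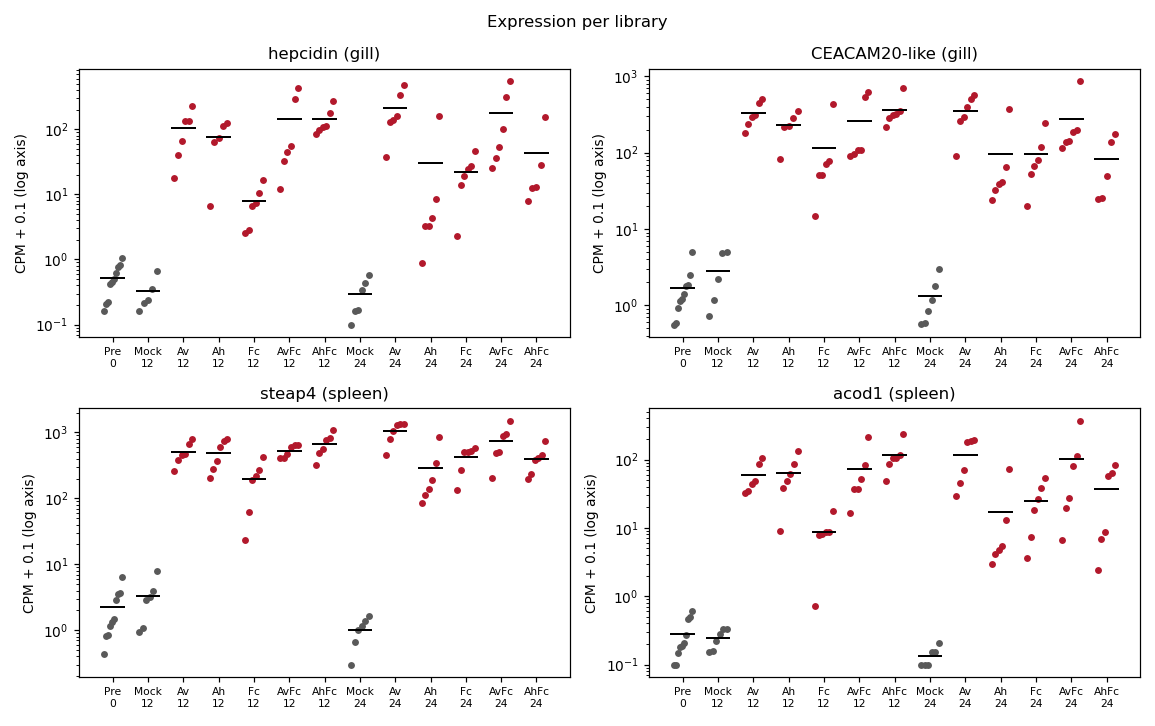
CPM in every library for hepcidin and the CEACAM20 gene in gill and for steap4 and acod1 in spleen. Each point is 1 library with 0.1 added for the log axis, and lines mark group means.

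Lists of inflammation, energy metabolism and protein folding rose in the spleen. Neutrophil genes (35) rose in 18 to 26 members per comparison (20 to 28 over the list alone), acute phase genes (25) in 8 to 11 (8 to 11), cytokine receptor and feedback genes (44), such as socs3a (4.72 ± 0.70, adjusted p = 3.51e-07) after AvFc at 12 h, in 13 to 27 (14 to 28), and complement genes (35) in 11 to 20 (11 to 20). Oxidative phosphorylation genes (52), such as atp5mc1 (2.81 ± 0.50, adjusted p = 7.07e-06) after AhFc at 24 h, rose in 30 to 50 members (37 to 51), heat shock and unfolded protein genes (56) in 18 to 37 (23 to 38), and glycolysis and hypoxia genes (44) in 15 to 27 (18 to 27). At 24 h 51 to 56 of 64 cell cycle genes rose after every infection (54 to 58), cdc6 by 3.26 ± 0.55 (adjusted p = 2.31e-06) after Av, and at 12 h 5 to 10 rose and 0 to 11 fell. The list test called all 10 comparisons for neutrophil, cytokine receptor, acute phase, heat shock, glycolysis and oxidative phosphorylation genes (adjusted p = 4.33e-22 to 0.0409), all but Fc at 12 and 24 h for complement (adjusted p = 0.00187 to 0.0211) and all at 24 h for cell cycle (adjusted p = 7.97e-35 to 1.68e-15) and Av at 12 h (0.00254, lost with DESeq2). None held in the spleen with an estimated correlation (adjusted p = 0.0808 to 0.718). The acute phase call after Fc at 12 h was lost without Mock A1, Fc M1, M3 or N2 (adjusted p up to 0.146), with no filter, limma-voom, the replicate or letter block, or without libraries rich in ribosomal protein transcripts, and the complement call after Ah at 24 h without Ah T3 (0.0508). A fit of the groups named alone ended all complement calls but Av at 24 h and AhFc at 12 h, and the acute phase calls after Fc and AvFc at 12 h and Ah and AvFc at 24 h.

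Lymphocyte, antigen presentation and blood cell lists fell in the spleen. B cell genes (36) fell in 9 to 25 members (12 to 28 over the list alone), T cell genes (27) in 5 to 21 (6 to 21), with tcf7 at -2.46 ± 0.33 (adjusted p = 1.85e-08), tbx21 at -2.59 ± 0.36 (adjusted p = 2.74e-08) and, against the rest, cd27 at 3.28 ± 0.47 (adjusted p = 6.65e-08) after Av at 24 h. MHC class II genes (30) fell in 6 to 18 (9 to 18), thrombocyte genes (16), such as the thrombopoietin receptor gene mpl (-3.54 ± 0.63, adjusted p = 1.11e-05) after AhFc at 12 h, in 2 to 10 (0 to 11), and erythrocyte genes (37) in 2 to 25 (1 to 28), most after AvFc at 12 h. The list test called B cell, T cell and erythrocyte genes in all 10 comparisons, class II genes in all but Fc at 24 h and thrombocyte genes in all but Fc at 12 h (adjusted p = 2.01e-08 to 0.0158), with adjusted p = 0.207 to 0.761 with an estimated correlation. Erythrocyte calls were lost without Av E3 at 12 h (adjusted p = 0.0656) and at 24 h without Mock A3, Ah J2 or Ah T3 for Ah (up to 0.084) and without AhFc R1 for AhFc (0.0746). Macrophage and dendritic genes (32) fell in 14 members after AvFc at 12 h (16, adjusted p = 0.0056, and adjusted p = 0.637 with an estimated correlation), such as mrc1a (-2.09 ± 0.59, adjusted p = 0.00421) and the iron exporter gene slc40a1 (-1.88 ± 0.46, adjusted p = 0.00087). Exocrine pancreas genes (31) fell in 20 members after AvFc at 12 h (23, median -4.14, adjusted p = 0.0029, and adjusted p = 0.686 with an estimated correlation).

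The other spleen lists had members on both sides. Ion transport genes (39) rose in 18 and fell in 5 members after Ah at 12 h (18 and 5, adjusted p = 0.0131, and adjusted p = 0.207 with an estimated correlation), a call that a fit of Ah and Mock alone did not make. Interferon-stimulated genes fell in 8 and rose in 4 members after Fc at 12 h (8 and 3, adjusted p = 0.0129, and 0.698 with an estimated correlation). Not called in the comparison with most changed members were inflammatory cytokines (18 higher and 11 lower of 52, AhFc at 12 h, adjusted p = 0.343), pattern recognition genes (9 and 11 of 49, Fc at 24 h, 0.258), interferon-stimulated genes (13 and 6 of 58, Fc at 24 h, 0.903) and MHC class I genes (10 and 9 of 38, AhFc at 24 h, 0.626). Antimicrobial genes (11 and 7 of 30, AhFc at 24 h, adjusted p = 0.818), epithelial genes (15 and 6 of 51, AhFc at 24 h, 0.525), extracellular matrix genes (16 and 10 of 50, Ah at 12 h, 0.748) and endothelial genes (9 and 3 of 28, Av at 12 h, 0.383) were not called. Liver (5 and 0 of 10, AhFc at 24 h, 0.417), skeletal muscle (8 and 2 of 23, Fc at 24 h, 0.137) and cartilage genes (0 and 3 of 14, Ah at 12 h, 0.336) were not called either. Named members were nccrp1 (4.16 ± 0.39, adjusted p = 4.44e-13) and pdia3 (2.61 ± 0.44, adjusted p = 3.37e-06) after AhFc at 24 h, cgas (2.44 ± 0.57, adjusted p = 0.000337) after Fc at 24 h and lyve1b (-3.64 ± 0.71, adjusted p = 7.03e-05) after Av at 12 h.

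Ribosomal protein genes took 14.4 to 27.8% of the counts in 9 infected spleen libraries and at most 10.9% in the others (spleen median 6.41%, gill median 4.82%). Of these 9, 2 were Fc at 12 h, 3 Fc at 24 h, 1 AhFc at 12 h, 2 AhFc at 24 h and 1 Ah at 12 h, and 0 were AvFc. Calls against Mock in spleen were made again without them, and only Fc at 24 h moved by more than 1.5 times.

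**Figure D4:**
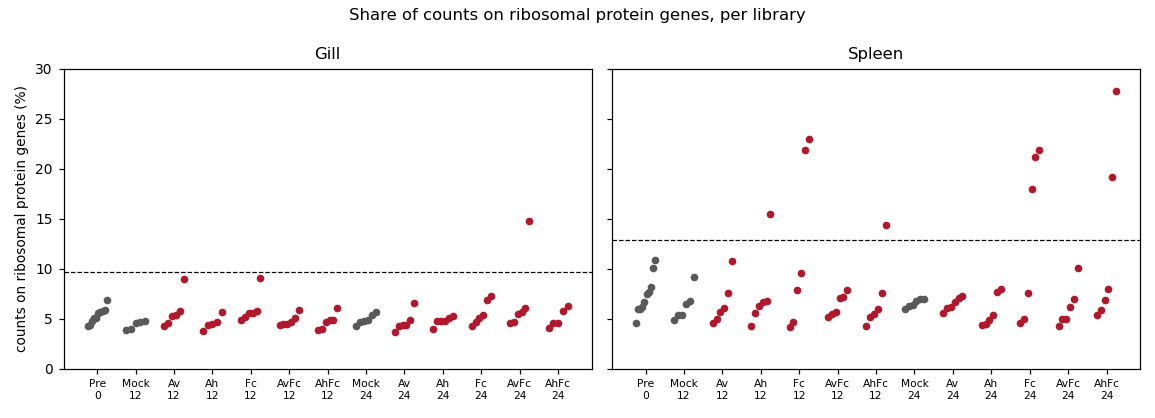
Share of counts on ribosomal protein genes in every library of gill and spleen. The dashed line marks 2 times the tissue median.

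AvFc against Av in gill gave 482 genes higher and 101 lower at 24 h (52 in all with limma-voom). There zgc:174917, a predicted dioxygenase gene, was higher by 4.67 ± 1.03 (adjusted p = 0.0106), irg1l, of the itaconate enzyme family, by 4.65 ± 0.97 (adjusted p = 0.00601), and the synaptic gene rims3 lower by 1.75 ± 0.39 (adjusted p = 0.0126), all lost in a fit of the 2 groups alone, which called 13 genes. These 583 calls became 1522 without AvFc O2, 1241 without Av F1 and 154 without Av E3. It became 142 without Av E1, 130 without Av F2 and 119 without Av F3. It became 92 without Av E2 and 67 without AvFc P3. Against Fc at 12 h AvFc had hepcidin (LOC119897237) higher by 4.21 ± 0.91 (adjusted p = 0.0162), with 179 genes higher and 186 lower, 0 in a fit of the 2 groups alone. Those 365 became 803 without Fc N2, 628 without Fc M3 and 210 without AvFc P1. It became 185 without Fc M1, 182 without AvFc P2 and 126 without Fc M2. It became 73 without Fc N3, 34 without AvFc O1 and 22 without AvFc O3. It became 13 without AvFc P3. AvFc against Fc at 24 h gave 4 higher and 1 lower, and these 5 became 62 without AvFc P1, 50 without AvFc O2 and 47 without AvFc O3. It became 19 without AvFc O1, 15 without AvFc P2 and 3 without Fc M2 or N3. It became 2 without Fc N1 or AvFc P3. AvFc against Av at 12 h gave 0 (1691 at unadjusted p under 0.05, 26 with DESeq2, 73 with limma-voom).

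For AhFc the gill differed from Ah at 12 h by 25 genes, all lower, among them a type II keratin (LOC119886878, -8.14 ± 1.32, adjusted p = 0.000511), which reached 0.723 without Ah T2. These 25 became 53 without Ah J1, 44 without Ah T3 and 43 without AhFc R1. It became 40 without Ah T2, 15 without AhFc R3 and 12 without AhFc Q2. It became 10 without AhFc Q1, 9 without AhFc Q3 and 8 without AhFc R2. It became 1 without Ah J3. Against Fc at 12 h 8 genes were higher, such as the sorting nexin gene snx10b (2.35 ± 0.48, adjusted p = 0.0221, lost without Fc M2, M3 or N3 or AhFc Q1, Q3 or R2, with adjusted p up to 0.134), and 3 lower, such as the spindle gene tacc3 (-1.52 ± 0.31, adjusted p = 0.0199, lost without Fc M2 or AhFc Q1 or Q3, with adjusted p up to 0.134). The 11 became 769 without Fc M1, 65 without AhFc R1 and 24 without Fc N1. It became 20 without Fc N2, 7 without Fc M3 or AhFc R2 and 4 without Fc N3. It became 0 without Fc M2, AhFc Q1 or Q3. At 24 h AhFc gave 0 genes against Ah (2091 at unadjusted p under 0.05, 50 with DESeq2, 0 with limma-voom, 5 without AhFc R2) and 0 against Fc (931 at unadjusted p under 0.05, 12 with DESeq2, 0 with limma-voom, 1 without Fc M1, M2, M3, N2 or N3).

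Single genes differed between coinfected and Fc spleen. Against Fc at 12 h AhFc had an L-amino-acid oxidase (LOC119918947), which releases hydrogen peroxide, higher by 6.86 ± 1.26 (adjusted p = 0.00155) and the calpain gene capn12 by 5.47 ± 1.22 (adjusted p = 0.00593). At 24 h AvFc had the transglutaminase gene tgm2l higher by 4.39 ± 0.84 (adjusted p = 0.00244), lost with limma-voom, in a fit of the 2 groups alone and without the libraries rich in ribosomal protein transcripts, and the antimicrobial peptide gene leap2 was higher too (adjusted p = 0.011, and 0.0985 without Fc N2). AvFc against Fc gave 456 genes higher and 1136 lower at 12 h (1592, 0 in a fit of the 2 groups alone) and 488 and 1827 at 24 h (2315, then 10), and AhFc against Fc 508 and 1039 at 12 h (1547, then 12) and 0 at 24 h (963 at unadjusted p under 0.05, 64 with DESeq2, 0 with limma-voom, 16 without AhFc Q2, 10 without AhFc Q1, 3 without AhFc R3). Without the libraries rich in ribosomal protein transcripts they were 242, 59 and 252. The 1592 became 2536 without Fc M3, 2500 without Fc N1 and 785 without AvFc P3. It became 705 without AvFc O3, 519 without Fc N2 and 491 without AvFc P1. It became 444 without AvFc O1, 279 without AvFc P2 and 89 without Fc M2, the 2315 became 4060 without Fc N1, 3881 without Fc M1 and 3602 without AvFc P3. It became 1342 without AvFc P1, 1205 without Fc N3 and 1001 without AvFc O2. It became 867 without AvFc O1, 673 without AvFc P2 and 557 without Fc M2. It became 77 without Fc N2, and the 1547 became 2762 without AhFc R3, 2433 without Fc M1 and 2423 without Fc M3. It became 910 without Fc N2, 834 without AhFc Q2 and 758 without AhFc R1. It became 510 without AhFc Q1, 482 without AhFc R2 and 252 without Fc M2.

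Against the Aeromonas infections AvFc spleen had 2 genes higher and 38 lower at 12 h, the largest fall being a ZP3 gene (LOC119899592) that reached adjusted p = 0.987 without Av F2. These 40 became 178 without Av E2, 173 without Av E3 and 133 without Av F1. It became 119 without Av E1, 11 without AvFc P1 or P2 and 10 without AvFc O1. It became 9 without Av F3, 8 without AvFc O2 and 7 without AvFc P3. It became 3 without AvFc O3. At 24 h AvFc gave 0 against Av (422 at unadjusted p under 0.05, 13 with DESeq2, 0 with limma-voom). AhFc gave 0 against Ah at 12 h (331 at unadjusted p under 0.05, 10 with DESeq2, 0 with limma-voom) and 517 higher and 8 lower at 24 h, such as the neuronal gene rundc3aa (3.55 ± 0.72, adjusted p = 0.0243, lost without AhFc Q3 or R2 or Ah J2, J3, T1 or T2, with adjusted p up to 0.455). These 525 became 1306 without AhFc R3, 1081 without AhFc Q2 and 1024 without AhFc Q1. It became 995 without AhFc R1, 201 without Ah T3 and 3 without AhFc R2. It became 0 without Ah J3, T2, J2, AhFc Q3 or Ah T1, and 0 without the libraries rich in ribosomal protein transcripts.

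Coinfection effects were also tested against the sum of the 2 single-infection effects on the log2 scale. In spleen at 24 h AvFc departed from the sum in 6935 genes, 2822 above and 4113 below, with the adhesion gene vcam1 (LOC119898683) above by 6.72 ± 1.07 (adjusted p = 4e-06). At 12 h 356 genes were above and 1896 below for AvFc, and for AhFc 399 and 1643 at 12 h and 515 and 1397 at 24 h. The 6935 fell to 4126 without the libraries rich in ribosomal protein transcripts, the 2252 for AvFc at 12 h became 3493 without Fc M3, 1314 without Av F2 and 853 without Fc N2, and the 2042 for AhFc became 3524 without AhFc R3, 3457 without Fc M3 and 928 without Ah T1. It became 556 without Fc N2. In gill at 12 h AvFc had 219 genes above and 371 below, with collagenase 3 (LOC119896105) below by 7.83 ± 1.47 (adjusted p = 0.00188, lost in a fit of the groups named alone, and 0.0714 without Fc M1). Gill AvFc at 24 h had 68 above and 145 below, and gill AhFc 2 and 51 at 12 h and 0 and 29 at 24 h. Without 1 library the 590 became 32 (Fc M1) to 1552 (Fc M3), moving by more than 1.5 times in 17 of 23 leave-outs. The 213 became 350 without Fc M2, 349 without AvFc P2 and 139 without Mock B3. It became 137 without Av F1, 134 without Mock A3 and 130 without Fc M1. It became 128 without Fc M3, 124 without Fc N1 and 82 without AvFc P3, the 53 became 364 without AhFc R1, 138 without Ah J1 and 95 without Fc M3. It became 30 without AhFc Q2, 22 without AhFc R2 and 21 without AhFc Q1. It became 13 without Mock A1, 11 without AhFc R3, Mock A2 or AhFc Q3 and 10 without Mock A3 or B1. It became 2 without Fc M1 and 0 without Ah J3, and the 29 became 56 without AhFc R1, 51 without Fc M2 and 47 without Ah T2. It became 19 without AhFc Q1 or R2, 18 without Fc M3 and 16 without Ah T3.

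Mock gill at 24 h differed from Pre in 1021 genes higher and 1651 lower. The zinc transporter gene slc30a8 was higher by 4.41 ± 0.59 (adjusted p = 1.91e-06) and a type I keratin (LOC119895804) by 2.24 ± 0.52 (adjusted p = 0.0025). The cytokine gene il17c was lower, 0.272 ± 0.233 CPM against 7.48 ± 10.1 CPM, by 4.72 ± 0.77 (adjusted p = 7.15e-05). Cell cycle genes were lower in 29 of 64 members (47 over the list alone, adjusted p = 2.36e-17, then 0.26 with an estimated correlation). Cytokine receptor genes were lower in 14 of 44 (19, adjusted p = 4.37e-08, then 0.155) and heat shock genes in 21 of 56 (23, adjusted p = 0.000208, then 0.506). Inflammatory cytokine, oxidative phosphorylation, neutrophil and antimicrobial genes were called lower too (adjusted p = 0.000281 to 0.0118, then 0.155 to 0.745), as were neutrophil genes at 12 h (0.000323, then 0.506). The rises of these lists start from a Mock below Pre. At 12 h Mock gill had 157 genes higher and 192 lower. Cytokine receptor (adjusted p = 1.71e-13), inflammatory cytokine (4.37e-08), MHC, B cell, T cell and cell cycle lists (up to 0.017) also differed there. None held with an estimated correlation. The 12 h changes of these lists start from that Mock. In spleen at 12 h 182 genes were higher and 92 lower, and at 24 h 3 higher and 8 lower. Without 1 library the 349 gill calls at 12 h became 70 (Mock B1) to 393 (Pre 7), and the 2672 at 24 h 1747 (Pre 8) to 3176 (Pre 7). The 274 in spleen became 25 (Mock A1) to 326 (Mock A3), and the 11 at 24 h 2 (Pre 1 or Mock A2) to 12 (Pre 4).

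In spleen at 24 h serotransferrin (tfa) was higher after Av by 3.73 ± 0.89 (adjusted p = 0.0316) and a siglec gene (LOC119898329) lower by 4.31 ± 0.84 (adjusted p = 0.0237), among 191 genes, 68 of them higher (both lost without Av E1, F1 or F3 or Ah J2, J3 or T2, and tfa also without Ah T1, with adjusted p up to 0.113). Spleen at 12 h gave 9 higher and 0 lower, and gill 13 and 155 at 12 h and 96 and 41 at 24 h. In gill at 12 h the immediate early gene fosb was lower after Av than after Ah (log2 fold change -5.37 ± 0.88, adjusted p = 0.000127, and 0.447 without Ah J3). In gill at 12 h epithelial barrier genes were lower after Av in 6 of 92 members (16 over the list alone, adjusted p = 4.26e-08, and adjusted p = 0.0496 with an estimated correlation). Skeletal muscle (4.26e-08) and erythrocyte genes (0.000133) were called higher there with 0 members passing, each with adjusted p = 0.618 with an estimated correlation. The epithelial call was 1 of 15 list calls in gill and 21 in spleen, and the others were lost with an estimated correlation. The 191 became 2819 in a fit of the 2 groups alone, 741 with DESeq2, 351 with limma-voom and 12 with the replicate block. In leave-outs the 191 became 918 without Ah T3, 634 without Av E2 and 37 without Av F2. It became 29 without Av E3, 12 without Ah T1 and 0 without Av E1, Ah J3, T2, Av F1, F3 or Ah J2, and the 9 became 26 without Av E3, 23 without Av E2 and 19 without Av F1. It became 14 without Av E1, 5 without Av F2, F3 or Ah T1 and 4 without Ah J1. It became 1 without Ah J3, T2, J2 or T3. The 168 in gill became 412 without Ah J1, 289 without Av F2 and 108 without Av E1. It became 103 without Av E3, 78 without Av F1 and 4 without Ah J3, and the 137 became 730 without Ah T3, 247 without Av E2 and 26 without Av E3. It became 7 without Av F3, 3 without Ah J2 and 0 without Av E1, F2, Ah J1, J3, T1, Av F1 or Ah T2.

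Infection effects that differed between 12 and 24 h were tested for all 5 infections together. In spleen 227 genes passed, among them 25 cell cycle genes, of which 3 still passed without Mock A1 at 12 h, the library rich in egg coat transcripts, where they had a median of 17 CPM against 3.55 in the other Mock 12 h libraries. The anillin-like gene si:dkey-30c15.10 (adjusted p = 7.51e-05), of the cleavage furrow, had log2 fold changes of -0.55 to 0.37 at 12 h and 1.62 to 2.08 at 24 h, and cdca3 (adjusted p = 0.000521) reached 2.07 to 2.76 and ube2t (adjusted p = 0.00102) 2.33 to 2.84 at 24 h. In gill 30 genes passed, with the type II keratin LOC119886878 (adjusted p = 0.000991) at 6.16 after Ah at 12 h and 6.31 after Fc at 24 h, and the immediate early gene egr1 (LOC119895561, adjusted p = 0.00514) at 3.32 after Ah at 12 h, and adjusted p = 0.207 without Ah J3 at 12 h. With limma-voom 0 gill genes passed. Chance was not excluded in either tissue. The 30 became 79 without Fc 12h M1, 66 without Ah 12h J1 and 46 without Fc 24h M3. It became 19 without Ah 24h J2, 15 without Ah 24h J1 and 9 without Ah 24h T1 or T2. It became 3 without Ah 12h J3, and the 227 became 573 without Fc 12h N2 and 74 without Mock 12h A1.

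The authors' deposited DESeq2 tables were compared with these calls at more than 2-fold. For infections against Mock their lists held 43.1% (gill, Fc at 24 h) to 93.8% (gill, Ah at 24 h) of the genes called here. Conversely 553 of their 569 genes were called here for Fc, and 120 of 180 for Ah. For gill AvFc at 24 h it was 1563 of 1625.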

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

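The tests of the ribosomal protein share were chosen after the libraries had been seen, as was the mean difference between the hours for cell cycle genes. The splits and the other tests had their predictions written after the pattern was seen and before the test was run. A rule for single libraries (Dixon, 95%) was applied 106 times, to 1 measure in 1 group each time, and found 20 values far from the others of their group, where chance flags about 1 in 20 groups, or 5.3.

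On ribosomal protein genes gill libraries Av 12 h F1 (8.95%), Fc 12 h M2 (9.05%), Ah 24 h T1 (3.99%) and AvFc 24 h P3 (14.8%) stood apart, as did spleen Ah 12 h T1 (15.5%) and AhFc 12 h R3 (14.4%). On erythrocyte genes gill Av 12 h F1 (3.94%), gill AvFc 24 h P3 (5.03%) and spleen Av 12 h F3 (12.9%) did. Spleen Ah 12 h J2 with 24.7 M counts and AhFc 12 h Q3 with 14.6 M stood apart in depth.

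For single genes, thymidine phosphorylase (LOC119895074) reached 298 CPM in gill AvFc 24 h P2. Collagenase 3 (LOC119896105) reached 2660.0 CPM in gill Fc 24 h M3, 22.6 CPM in gill Mock 12 h B2 and 7640.0 CPM in gill AhFc 12 h R1. Fosl1a reached 801 CPM in gill Ah 12 h J3, and haptoglobin (LOC119890332) 2470.0 CPM in spleen AhFc 24 h Q3. The MFAP4-like gene (LOC119915509) reached 1.39 CPM in spleen Mock 24 h A1. The ZP3 gene LOC119899592 reached 1540.0 CPM in spleen Mock 12 h A1 and 0.167 CPM in spleen Ah 12 h J1.

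Infection effects differed between the hours for 30 gill and 227 spleen genes by a test of the difference. In gill these were led by LOC119886878 (adjusted p = 0.000991, edgeR), si:ch73-335l21.4, LOC119882934 and LOC119895561 (each adjusted p = 0.00514), ier2a (adjusted p = 0.00605) and LOC119886035 (adjusted p = 0.00648). None of these 6 was called with limma-voom. Without Ah 12 h J3 adjusted p became 0.284 for si:ch73-335l21.4, 0.207 for LOC119895561, 0.136 for ier2a and 0.23 for LOC119886035, and without AvFc 24 h P3 it became 0.488 for LOC119882934. In spleen they were si:dkey-30c15.10 (adjusted p = 7.51e-05, edgeR), cks1b and cdca3 (each adjusted p = 0.000521), sgo1 (adjusted p = 0.00054), and dbpa and ube2t (each adjusted p = 0.00102). For 2 genes called in 1 tissue the estimate in the other lay on the other side without passing, and the difference between the tissues was not tested. LOC119893837 fell by 4.51 in gill after Ah at 12 h and had 2.93 in spleen (adjusted p = 0.0837, edgeR), and LOC119896726 fell by 10.82 in spleen after AhFc at 24 h and had 0.55 in gill (adjusted p = 0.733).

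Libraries were split into groups of the same sizes 50 times, the real split included, in fits of the groups named alone. Single libraries were moved across letters, and each treatment has its own letters. No split can therefore tell treatment from letter, and chance here means the placing of single libraries. For infections against Mock the real split alone (1 of 50, the lowest value possible) called as many genes as it did. Such chance can be excluded, except in gill Fc at 12 h. There the real split called 0 (another 2), which all 50 of 50 reach by necessity, so this says nothing on the calls of the full fit. Some other splits called many genes there too, up to 984 against 2419 in gill AhFc at 12 h, 772 against 5203 in gill Av at 24 h, 759 against 9825 in spleen AvFc at 12 h, 4086 against 11881 in spleen Av at 24 h, 4567 against 8344 in spleen Fc at 24 h and 3312 against 9192 in spleen AvFc at 24 h.

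For coinfections against single infections the real split often called 0 genes, so that all 50 of 50 reach it by necessity and nothing is learnt on the calls of the full fit. In gill this was so for AvFc against Av at 12 h, AvFc against Fc at 12 and 24 h, AhFc against Ah at 12 and 24 h and AhFc against Fc at 24 h. In spleen it was so for AvFc against Av and AhFc against Ah at both hours, AvFc against Fc at 12 h and AhFc against Fc at 24 h. In the last, another split called 3184 genes (83 in gill). In gill AvFc against Av at 24 h another called 361 against 13 (2 of 50), so chance is not excluded. The cause of these large counts in other splits was not tested. Chance was excluded (1 of 50) for AhFc against Fc at 12 h in gill (7) and spleen (12) and for spleen AvFc against Fc at 24 h (10).

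For non-additivity the splits mixed the libraries of all 4 groups, Mock included. They ask whether any of the groups differ, so they cannot decide whether the single effects add. For AvFc 1 of 50 called as many genes in each tissue and hour. For AhFc it was 3 of 50 in gill at 24 h (2 genes, another split 3224), 3 of 50 in spleen at 12 h (373, another 2265) and 4 of 50 in spleen at 24 h (1723, another 3381). In gill at 24 h and spleen at 12 h the other split for AhFc called several times the real count, and the cause was not tested. Chance was excluded for Mock against Pre (1 of 50) in gill and in spleen at 12 h, and for Av against Ah in spleen at 24 h (1 of 50, 2819 genes, another split 470), and not for Av against Ah in gill at 24 h (4 of 50, 6 genes, another 232). With a real count of 0 nothing is learnt for AhFc non-additivity in gill at 12 h, Mock against Pre in spleen at 24 h and Av against Ah at 12 h in both tissues (50 of 50). For the tests of time chance was not excluded, as 3 of 50 splits called as many genes (18 in gill, another 31, and 230 in spleen, another 1681).

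The 9 infected spleen libraries rich in ribosomal protein transcripts were weighed first. Shallow libraries (3 of the 9 below their group's median total) and the mapping-rate note (2 of the 9) are excluded as causes. Genomic DNA stays open, as a high ribosomal share can itself keep detected genes low (0 of the 9 above the group median). Infection may contribute, but 9 of 60 infected against 0 of 22 other libraries (exact p = 0.104) cannot tell. Nor can 8 of 36 with Fc against 1 of 24 without (exact p = 0.0721).

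The egg coat transcripts of spleen Mock 12 h A1 were weighed second. RNA of ovary in the dissected spleen could explain them, since 6 of 8 measured oocyte genes outside that family were highest in A1, among them h1m (214 CPM) and zar1 (63.6 CPM). A library of another tissue under a spleen label is excluded, because A1 correlated at 0.941 with the other spleen Mock 12 h libraries and at 0.753 with gill Mock.

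The rise of cell cycle genes between 12 and 24 h in infected spleens was weighed last, with 25 of 64 called by the test of time. Over all 64, a fall in Mock other than A1 is excluded (median change 0.11, -0.25 with A1). So are the libraries rich in ribosomal protein transcripts, without which 24 were still called. The ovary RNA in A1 may account for calls of the test of time, as 3 remained without A1. These genes had a median of 17 CPM in A1 and 3.55 in the other Mock 12 h libraries. The mean difference over the 5 infections had a median of 2.5 (24 of the 25 called) and without A1 of 1.73 (14 called). These genes had been chosen by the test of time with A1 in, so this leaves open how much of the difference the ovary RNA explains.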

How the results depend on the processing

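Of 56 counts 27 stayed within 1.5 times under DESeq2, 30 under limma-voom, 31 with the library letter as a random block, 27 in fits of only the groups named, 39 without libraries rich in ribosomal protein transcripts, 53 with no filter and 55 with DESeq2 size factors or thinning. For those that moved the value is given, and the cause was not tested. The alternatives on ribosomal protein transcripts and on depth were added after the data were seen. Putting back the 3 gill libraries that the authors excluded could not be run, as the count tables do not hold them.

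DESeq2 gave in gill 252 for Ah against Mock at 24 h, 26 for AvFc against Av at 12 h, 1076 for AvFc against Fc at 12 h and 73 for AhFc against Ah at 12 h. It gave 188 for AhFc against Fc at 12 h, 1113 for AvFc against Av at 24 h, 109 for AvFc against Fc at 24 h and 50 for AhFc against Ah at 24 h. It gave 12 for AhFc against Fc at 24 h, 1465 for AvFc non-additivity at 12 h, 162 for AhFc non-additivity at 12 h and 433 for AvFc non-additivity at 24 h. It gave 95 for AhFc non-additivity at 24 h, 794 for Mock at 12 h against Pre, 308 for Av against Ah at 12 h and 401 for Av against Ah at 24 h. It gave 124 for the test of time. DESeq2 gave in spleen 210 for AvFc against Av at 12 h, 2793 for AvFc against Fc at 12 h, 10 for AhFc against Ah at 12 h and 2525 for AhFc against Fc at 12 h. It gave 13 for AvFc against Av at 24 h, 1245 for AhFc against Ah at 24 h, 64 for AhFc against Fc at 24 h and 502 for Mock at 12 h against Pre. It gave 65 for Mock at 24 h against Pre, 40 for Av against Ah at 12 h, 741 for Av against Ah at 24 h and 689 for the test of time.

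Limma-voom gave in gill 545 for Ah against Mock at 12 h, 1327 for Fc against Mock at 12 h, 46 for Ah against Mock at 24 h and 73 for AvFc against Av at 12 h. It gave 241 for AvFc against Fc at 12 h, 1 for AhFc against Ah at 12 h, 6 for AhFc against Fc at 12 h and 52 for AvFc against Av at 24 h. It gave 0 for AvFc against Fc at 24 h, 305 for AvFc non-additivity at 12 h, 0 for AhFc non-additivity at 12 h and 55 for AvFc non-additivity at 24 h. It gave 3 for AhFc non-additivity at 24 h, 32 for Av against Ah at 12 h and 0 for the test of time. Limma-voom gave in spleen 0 for AvFc against Av at 12 h, 865 for AvFc against Fc at 12 h, 985 for AhFc against Fc at 12 h and 96 for AvFc against Fc at 24 h. It gave 0 for AhFc against Ah at 24 h, 1201 for AvFc non-additivity at 12 h, 1092 for AhFc non-additivity at 12 h and 0 for Av against Ah at 12 h. It gave 351 for Av against Ah at 24 h and 149 for the test of time. Limma-voom gave 102 for the named genes kept.

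Limma-voom with the library letter as a random block gave in gill 441 for Ah against Mock at 12 h, 1015 for Fc against Mock at 12 h, 45 for Ah against Mock at 24 h and 2 for AvFc against Av at 12 h. It gave 134 for AvFc against Fc at 12 h, 1 for AhFc against Ah at 12 h, 5 for AhFc against Fc at 12 h and 42 for AvFc against Av at 24 h. It gave 0 for AvFc against Fc at 24 h, 85 for AvFc non-additivity at 12 h, 0 for AhFc non-additivity at 12 h and 38 for AvFc non-additivity at 24 h. It gave 0 for AhFc non-additivity at 24 h, 162 for Mock at 12 h against Pre, 16 for Av against Ah at 12 h and 0 for the test of time. Limma-voom with the library letter as a random block gave in spleen 0 for AvFc against Av at 12 h, 568 for AvFc against Fc at 24 h, 0 for AhFc against Ah at 24 h and 1056 for Mock at 12 h against Pre. It gave 116 for Mock at 24 h against Pre, 0 for Av against Ah at 12 h, 660 for Av against Ah at 24 h and 123 for the test of time. Limma-voom with the library letter as a random block gave 101 for the named genes kept.

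A fit of only the groups named gave in gill 471 for Ah against Mock at 12 h, 0 for Fc against Mock at 12 h, 2351 for AvFc against Mock at 12 h and 5203 for Av against Mock at 24 h. It gave 4706 for AhFc against Mock at 24 h, 0 for AvFc against Fc at 12 h, 0 for AhFc against Ah at 12 h and 7 for AhFc against Fc at 12 h. It gave 13 for AvFc against Av at 24 h, 0 for AvFc against Fc at 24 h, 18 for AvFc non-additivity at 12 h and 0 for AhFc non-additivity at 12 h. It gave 2 for AhFc non-additivity at 24 h, 0 for Av against Ah at 12 h, 6 for Av against Ah at 24 h and 18 for the test of time. A fit of only the groups named gave in spleen 3480 for Fc against Mock at 12 h, 7461 for Ah against Mock at 24 h, 0 for AvFc against Av at 12 h and 0 for AvFc against Fc at 12 h. It gave 12 for AhFc against Fc at 12 h, 10 for AvFc against Fc at 24 h, 0 for AhFc against Ah at 24 h and 1116 for AvFc non-additivity at 12 h. It gave 373 for AhFc non-additivity at 12 h, 0 for Mock at 24 h against Pre, 0 for Av against Ah at 12 h and 2819 for Av against Ah at 24 h. A fit of only the groups named gave 113 for the named genes kept.

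Leaving out libraries rich in ribosomal protein transcripts gave in gill 831 for AvFc against Fc at 12 h, 33 for AhFc against Fc at 12 h, 67 for AvFc against Av at 24 h and 2 for AvFc against Fc at 24 h. It gave 1317 for AvFc non-additivity at 12 h and 82 for AvFc non-additivity at 24 h. Leaving out libraries rich in ribosomal protein transcripts gave in spleen 5589 for Fc against Mock at 24 h, 242 for AvFc against Fc at 12 h, 252 for AhFc against Fc at 12 h and 59 for AvFc against Fc at 24 h. It gave 0 for AhFc against Ah at 24 h, 4126 for AvFc non-additivity at 24 h, 915 for AhFc non-additivity at 24 h and 691 for Mock at 12 h against Pre. It gave 21 for Mock at 24 h against Pre, 3 for Av against Ah at 12 h and 814 for Av against Ah at 24 h.

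No filter on low counts gave in gill 75 for Av against Ah at 24 h. No filter on low counts gave in spleen 86 for AvFc against Av at 12 h and 586 for Mock at 12 h against Pre. DESeq2 size factors in place of TMM gave in gill 21 for AhFc against Fc at 12 h. Thinning deeper libraries to the median depth gave in gill 19 for AhFc against Fc at 12 h.

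Libraries of different treatments share only a number, and those of the 2 hours of a treatment also a letter. Residuals of libraries with the same number correlated at a mean of -0.003 in gill and 0.004 in spleen, and 21 of 69 gill and 31 of 72 spleen libraries correlated best with their own number. With the replicate block 38 of 52 counts stayed within 1.5 times. The replicate block gave in gill 12 for AhFc against Ah at 12 h, 5 for AhFc against Fc at 12 h, 3 for AvFc against Fc at 24 h and 2 for AhFc against Ah at 24 h. It gave 367 for AvFc non-additivity at 12 h, 11 for AhFc non-additivity at 12 h, 132 for AvFc non-additivity at 24 h and 31 for Av against Ah at 24 h. It gave 8 for the test of time. The replicate block gave in spleen 2 for AvFc against Av at 12 h, 1048 for AvFc against Fc at 12 h, 0 for AhFc against Ah at 24 h and 1 for Av against Ah at 12 h. It gave 12 for Av against Ah at 24 h.

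Leaving out 1 library at a time gave in gill 70 to 393 for Mock at 12 h against Pre, 1747 to 3176 for Mock at 24 h against Pre and 1394 to 2344 for Av against Mock at 12 h. It gave 320 to 1862 for Ah against Mock at 12 h, 142 to 3310 for Fc against Mock at 12 h and 726 to 1471 for AvFc against Mock at 12 h. It gave 1212 to 3011 for AhFc against Mock at 12 h, 32 to 1552 for AvFc non-additivity at 12 h and 0 to 364 for AhFc non-additivity at 12 h. It gave 3 to 79 for the test of time, 4 to 412 for Av against Ah at 12 h and 1 to 53 for AhFc against Ah at 12 h. It gave 13 to 803 for AvFc against Fc at 12 h, 0 to 769 for AhFc against Fc at 12 h and 43 to 168 for Ah against Mock at 24 h. It gave 1284 to 4339 for Fc against Mock at 24 h, 794 to 3069 for AhFc against Mock at 24 h and 82 to 350 for AvFc non-additivity at 24 h. It gave 16 to 56 for AhFc non-additivity at 24 h, 67 to 1522 for AvFc against Av at 24 h and 0 to 730 for Av against Ah at 24 h. It gave 0 to 5 for AhFc against Ah at 24 h, 2 to 62 for AvFc against Fc at 24 h and 0 to 1 for AhFc against Fc at 24 h. Leaving out 1 library at a time gave in spleen 25 to 326 for Mock at 12 h against Pre, 2 to 12 for Mock at 24 h against Pre and 4035 to 7601 for Fc against Mock at 12 h. It gave 853 to 3493 for AvFc non-additivity at 12 h, 556 to 3524 for AhFc non-additivity at 12 h and 74 to 573 for the test of time. It gave 3 to 178 for AvFc against Av at 12 h, 1 to 26 for Av against Ah at 12 h and 89 to 2536 for AvFc against Fc at 12 h. It gave 252 to 2762 for AhFc against Fc at 12 h, 0 to 918 for Av against Ah at 24 h and 0 to 1306 for AhFc against Ah at 24 h. It gave 77 to 4060 for AvFc against Fc at 24 h and 0 to 16 for AhFc against Fc at 24 h. The other 16 counts stayed within 1.5 times.

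Of the list calls, 511 of 553 kept direction and threshold under DESeq2, 536 under limma-voom and 513 in fits of only the groups named. Over all leave-outs 7149 list values did and 472 did not pass. A few turned direction, and the cause was not tested. Under DESeq2 skeletal muscle genes turned in gill, for Ah against Mock at 24 h (adjusted p = 0.935) and AvFc against Fc at 12 h (adjusted p = 0.0327). Without libraries rich in ribosomal protein transcripts oxidative phosphorylation genes turned in spleen for AvFc against Fc (adjusted p = 0.000147) and AhFc against Fc at 24 h (adjusted p = 0.000284), and exocrine pancreas genes for AhFc against Fc at 24 h (adjusted p = 0.466). Leaving out 1 library gave adjusted p = 3.55e-06 to 0.782 for those pancreas genes, turning without AhFc Q3, and adjusted p = 6.45e-07 to 0.954 for those oxidative phosphorylation genes, turning without Fc M2 (adjusted p = 0.788).

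Among named genes LOC119899595 in the spleen AhFc non-additivity at 12 h had log2 changes of -0.13 to 10.84, the lowest without Mock A1. LOC119895804 in spleen AhFc against Mock at 24 h turned to -0.19 without libraries rich in ribosomal protein transcripts. LOC119884033 in spleen went to 0 for Ah at 12 h without those libraries and without Ah T1 (0 to 9.63 over leave-outs), and for Av at 12 h without Av F2 (0 to 9.09). With another scaling the share of higher genes moved by more than 10 points only for spleen Mock at 24 h against Pre, from 27.3% to 44.4%.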

Other observations

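Some list members that the report did not name also changed. In gill after AvFc at 24 h erythrocyte genes moved both ways, 6 higher and 11 lower, and 2 hemoglobin beta genes, of oxygen transport, were among the higher. LOC119891473 rose by 5.03 ± 1.01 (adjusted p = 0.00015, edgeR) and LOC119891466 by 3.54 ± 0.86 (adjusted p = 0.00122). A claudin-34 gene (LOC119900398), of tight junctions, rose by 5.66 ± 0.96 (adjusted p = 1.58e-05).

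In spleen after AhFc at 24 h genes of MHC class I antigen processing moved both ways, 10 higher and 9 lower. A class I alpha chain gene (LOC119908113), of peptide display to T cells, was among the lower (log2 fold change -2.58 ± 0.67, adjusted p = 0.00139, edgeR). The endothelial genes plvapa and pecam1 rose after Av at 12 h by 2.09 ± 0.49 (adjusted p = 0.00073) and 1.54 ± 0.36 (adjusted p = 0.000635).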
